A study of Homo sapiens with 6 samples.

How the data were processed

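RNA from 2 human lung cell lines was measured by paired-end sequencing of polyadenylated RNA, with 3 libraries of IMR90hTERT fibroblasts and 3 of 16HBE bronchial epithelial cells. Per the labels' protocols, the cells grew in medium with 10% fetal bovine serum and the RNA had an integrity number (RIN) over 8. Samples were grouped by the cell line their labels give.

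Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7 and cutadapt 4.6 and transcripts were quantified with Salmon, whose version those notes print as 1.10.11, on the genome build hg38. The values deposited by the authors are TPM per gene, transcript abundances that are scaled for transcript length and sum to 1000000 in each library. The annotation release, and whether the quantification used strand, are not given in the sources used here. Because each library sums to the same total, genes that are very abundant in one line lower the TPM of all others there. TPM keeps no depth, so no read totals, counting intervals or detection limits are given, and a gene at 0 is described only as listed at 0. Estimates for genes with near-identical copies, and for genes that overlap on opposite strands, are uncertain. All 6 columns of values were used. Of the gene identifiers, 92.07% were found in GENCODE release 29 with the version ignored, and coordinates and gene types were taken from that release.

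TPM values were analysed as log2(TPM + 1), so fold changes of low genes are understated. Genes with a TPM of at least 1 in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (a linear model per gene, with moderated variances that follow a trend in expression, two-sided). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 with a log2 fold change of at least 1 in size. A gene counted as expressed in a line at a TPM of at least 1 in all 3 libraries, and as restricted to it when also below 0.1 in all 3 of the other line. For the 28 gene lists fixed before the data were examined, limma's camera was run with a preset correlation between genes of 0.01 on the 27 lists with at least 5 tested members, with adjustment over those lists. The estimated correlation and fry, which tests a list's own members without comparing them with other genes, were alternatives. With an estimated correlation, camera also uses the residual degrees of freedom of the 6 libraries in place of those of all genes. This raises small p-values. Of the fixed symbols, 2 were not matched to the gene names used. Values per library were compared with exact permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

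The genes named were chosen by a rule set before the data were examined. It takes HHIP and TERT, the 10 largest changes per direction among called genes with a mean TPM of at least 10 in the higher line and no overlap between lines, up to 4 called members per list with the largest changes, any tested hedgehog or COPD locus gene, the 5 most abundant genes per line and the 5 most abundant restricted genes per line. Y-linked genes and XIST were left out of these choices and of the plots. Some genes that the rule or a small count would name are not reported here.

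Alternatives varied the pseudocount, the filter on low values, the scaling between libraries, the variance model, the fold threshold, the set test, the limits for expressed genes and the use of the replicate number as a block, and left out each library in turn. Fits that left out a library required a TPM of at least 1 in 2 libraries, the size of the smaller group. The scripts were tested on simulated values for 14933 genes in the comparison of 16HBE with IMR90hTERT. They recovered 92.5% of genes changed by a log2 fold of 1.5 and 100% of those changed by 2.5 or 4, and called 0.034% of 14733 unchanged genes. The simulation changed few genes, drew normal noise and held no shift common to all genes, so its rates need not hold for these data. A planted list was found, and 0 of 50 lists without a change were called by camera; the simulated genes varied independently, so this says nothing of lists whose genes vary together.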

Results

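RNA from 2 human lung cell lines was compared. IMR90hTERT is a line of fetal lung fibroblasts, the matrix-producing cells of connective tissue, made to divide without limit by expression of the catalytic subunit of telomerase. 16HBE is a line of bronchial epithelial cells, which line the conducting airways, and it was used here without treatment. Each line was represented by 3 libraries of polyadenylated RNA, 6 in all, and the values are TPM, transcript abundances scaled to a total of 1000000 per library, for each annotated gene, of which 42640 carried a symbol and 20601 an identifier alone. TPM keeps no read totals, so the depth of each library is unknown here and no interval from counting can be given; the labels state an average of about 50 M reads. Nothing in the labels says that the 3 libraries of a line came from separate cultures, so p-values measure the spread between these libraries, which may be technical. On the log2(TPM + 1) scale, libraries of the same line correlated across genes with Pearson's r of 0.973 to 0.985, and libraries of different lines with r of 0.705 to 0.735; genes are not independent replicates. The first principal component separated the lines and held 91.8% of the variance. The second held 3.1% and set IMR90hTERT libraries 1 and 2 apart from each other. Transcripts of the mitochondrial genome took between 6.05% and 7.56% of the TPM of a library.

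The labels give the purpose of the data as deciding which genes each line expresses, for use in networks of interacting proteins. With expression defined as a TPM of at least 1 in all 3 libraries, 16HBE expressed 13408 genes and IMR90hTERT expressed 12566, and 11387 genes met the rule in both. Of the expressed genes, 11649 in 16HBE and 11291 in IMR90hTERT were protein-coding. The number of genes at a TPM of at least 1 was 14510.7 ± 64.3 per library in 16HBE and 13557.3 ± 112.4 in IMR90hTERT (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). A stricter rule, expression in 1 line and a TPM below 0.1 in every library of the other, was met by 500 genes in 16HBE and 332 in IMR90hTERT. Among the most abundant of these in 16HBE were KRT19 (a keratin of simple epithelia, 473 ± 69.1 TPM), LCN2 (an iron-binding secreted protein, 421 ± 345), S100A9 (a calcium-binding inflammatory protein, 411 ± 226) and SAA1 (an acute-phase protein with a close paralog, 392.2 ± 134; SD, n = 3 each). These 4 were listed at 0 in the 3 IMR90hTERT libraries. In IMR90hTERT the most abundant restricted genes were COL6A3 (2702 ± 161 TPM), COL3A1 (2396 ± 189), POSTN (1681 ± 560), DCN (1481 ± 701) and GREM1 (1041 ± 127; SD, n = 3 each), which encode 2 collagens, periostin, decorin and a secreted BMP antagonist. The counts of restricted genes depend on the limits used: with a TPM of at least 5 required in the expressing line, they were 209 and 144. Between 16HBE libraries LCN2 was uneven, at 322, 137 and 805 TPM. A further 36031 genes were listed at 0 in all 6 libraries.

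HHIP, the hedgehog-interacting protein named in the series title, was detected in the fibroblast line and listed at 0 in the epithelial line. HHIP binds hedgehog ligands at the cell surface and thereby dampens the pathway. Its gene, ENSG00000164161.10, lies on the plus strand of chromosome 4 from position 144646021 to 144745271 of hg38. Its level was 4.17, 1.28 and 2.40 TPM in IMR90hTERT libraries 1, 2 and 3, a mean of 2.62 ± 1.46 (SD, n = 3), and the 3 16HBE libraries were listed at 0 (limma, Benjamini-Hochberg adjusted p = 0.000713). The variance behind this p-value pools the 16HBE libraries, which have no spread, and so is below that among IMR90hTERT libraries. Other genes listed at 0 in 1 line share this pooling. With 16HBE at 0 the log2 fold change of HHIP is set by the pseudocount, at -1.77 with 1, -2.53 with 0.5 and -4.615 with 0.1. With a pseudocount of 1 and tested against a log2 fold change of 1 instead of 0, HHIP did not pass (adjusted p = 0.0598). The start of HHIP overlaps an antisense gene, HHIP-AS1, on the minus strand of chromosome 4 from 144642922 to 144661357. HHIP-AS1, looked up after the values of HHIP were seen, stood at 2.67, 1.67 and 3.56 TPM in the IMR90hTERT libraries and at 0, 0.115 and 0.126 in the 16HBE libraries. Whether the quantification used strand is not given in the sources used here, so reads from the overlap of the 2 genes cannot be assigned with certainty. TERT, the gene for the introduced telomerase subunit, served as a check of the labels. TERT (ENSG00000164362.21) lies on the minus strand of chromosome 5 from 1253147 to 1295069. It reached 204.5 ± 32.7 TPM in IMR90hTERT and 1.04 ± 0.57 in 16HBE (SD, n = 3 each), with a log2 fold change of -6.68 (SE 0.215, limma adjusted p = 1.03e-07), 16HBE minus IMR90hTERT, as in all fold changes given here. Transcripts of the transgene and of the resident gene are not separated in these values.

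Genes of hedgehog signalling, the pathway that HHIP acts on, were compared as a list. Of its 28 genes, 22 passed the filter on low values. Of these, 13 were higher in IMR90hTERT, 2 were higher in 16HBE and 7 were not called. The transcription factors of the pathway were among those higher in IMR90hTERT. GLI1, also a target, had 5.08 ± 3.54 TPM against 0.116 ± 0.0967, GLI2 had 13.4 ± 3.93 against 0.214 ± 0.242, and GLI3 had 6.24 ± 0.64 and was listed at 0 in 16HBE. GLI1 was uneven among the IMR90hTERT libraries, at 2.07, 8.97 and 4.19 TPM. PTCH1, the receptor and a target gene, had 12.4 ± 4.79 TPM in IMR90hTERT and 3.48 ± 0.72 in 16HBE (log2 fold change -1.52, SE 0.295). The coreceptors GAS1, CDON and BOC were higher in IMR90hTERT, with log2 fold changes of -1.68, -1.29 and -2.81. FOXF1 and FOXL1, transcription factors of lung mesenchyme, had 132.9 ± 18.4 and 31.1 ± 6.27 TPM there; FOXF1 was listed at 0 in 16HBE and FOXL1 had 1.15 ± 1.42. Higher in 16HBE were HHAT, which attaches palmitate to the ligands (8.64 ± 1.12 against 1.08 ± 0.23 TPM), and the kinase GRK2 (85.2 ± 6.82 against 28.0 ± 3.18). SMO, the signal transducer, was not called, with 11.6 ± 1.13 TPM in 16HBE and 10.0 ± 1.52 in IMR90hTERT (log2 fold change 0.20, SE 0.162, limma adjusted p = 0.309); its sign turned under both scalings that centre the genes, to -0.20 and -0.15. The ligand SHH, named after its values were seen, was at 0.0105 ± 0.0182 TPM in 16HBE and 0.0192 ± 0.0168 in IMR90hTERT. The camera set test placed the list lower in 16HBE relative to other genes (adjusted p = 0.000462), and the adjusted p was 0.0898 with an estimated correlation. That estimate, -0.00584, was below the preset 0.01, so members varying together do not account for the higher value.

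**Figure D1:**
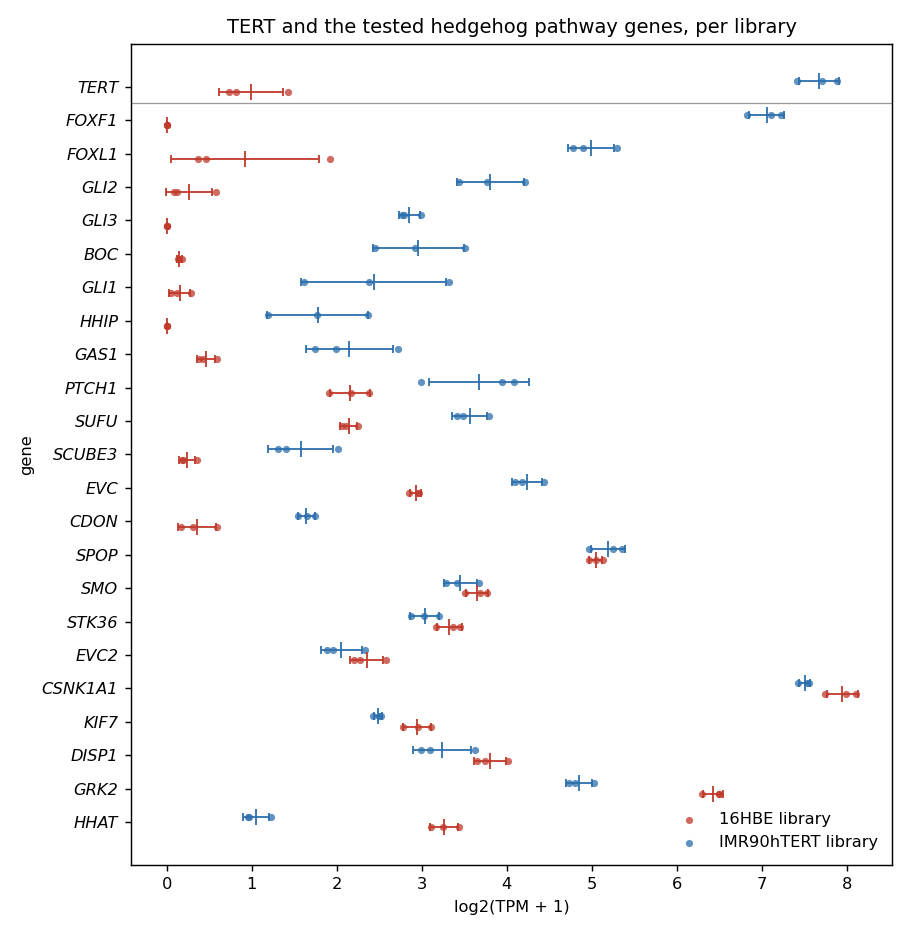
Expression of TERT and of the 22 tested hedgehog pathway genes as log2(TPM + 1) on the horizontal axis, with 1 gene per row; points are single libraries, ticks are means and bars are SDs of 3 libraries per line. HHIP lies at 0 in the 3 16HBE libraries and between 1.28 and 4.17 TPM in IMR90hTERT, and 13 genes were higher in IMR90hTERT.

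Genes at or near loci associated with chronic obstructive pulmonary disease (COPD) or lung function were split between the lines. Of 31 tested genes, 6 were higher in 16HBE, 8 were higher in IMR90hTERT and 17 were not called. Higher in 16HBE were SERPINA1, the gene for alpha-1 antitrypsin (26.2 ± 6.97 against 0.318 ± 0.146 TPM), the adhesion receptor ADGRG6 (93.9 ± 12.7 against 6.63 ± 2.40), the nicotinic receptor subunit CHRNA5 (15.5 ± 2.40 against 1.41 ± 1.21), ARMC2, AGER and GSTCD. AGER under quantile normalization (0.80) and GSTCD under both centring scalings (0.89 and 0.94) lay below the fold threshold. Higher in IMR90hTERT beside HHIP were the collagenase MMP1 (74.0 ± 35.9 against 0.0167 ± 0.0289 TPM), TNS1, a focal adhesion protein (61.9 ± 11.7 against 0.902 ± 0.521), the integrin subunit ITGA1 (65.4 ± 5.44 against 1.96 ± 0.86), ADAM19, PID1, STN1 and THSD4. THSD4 had a log2 fold change of -1.04 and lost its call when IMR90hTERT replicate 2 or 16HBE replicate 1 or 2 was left out, at -0.85, -0.99 and -0.997. FAM13A, a gene of another locus associated with COPD, was not called, with 7.83 ± 2.51 TPM in 16HBE and 10.6 ± 1.31 in IMR90hTERT (log2 fold change -0.42, SE 0.225, limma adjusted p = 0.127). The median log2 fold change of the list was 0.14, its mean was -0.24, and the set test leaned lower in 16HBE without passing (camera adjusted p = 0.204, and an adjusted p of 0.568 with an estimated correlation).

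Across the genome the lines differed in 5865 of 14933 tested genes, or 39.3%, with 3946 higher in 16HBE and 1919 higher in IMR90hTERT (limma, adjusted p below 0.05 and a log2 fold change of at least 1 in size). For 73.6% of all tested genes, every library of one line lay above every library of the other, against 10% by chance in 3 against 3. The 10 largest differences in favour of 16HBE included those in KRT81, MAL2, C15orf48, C19orf33, KRT19, SAA1, S100A9, EPCAM and LCN2. KRT81, a keratin with closely related neighbours, had 952 ± 322 TPM against 0.248 ± 0.17 (log2 fold change 9.52, SE 0.262). MAL2, which acts in transport across polarized epithelia, had 757 ± 77.3 against 0.266 ± 0.24 (9.24, SE 0.162). The 10 largest in favour of IMR90hTERT were in COL1A2, COL6A3, COL3A1, IGFBP5, POSTN, COL1A1, DCN, ACTG2, GREM1 and VIM. COL1A2, a chain of type I collagen, had 6302 ± 385 TPM against 0.0907 ± 0.0465 (log2 fold change -12.5, SE 0.105). VIM, the intermediate filament protein of mesenchymal cells, had 3449 ± 188 against 2.86 ± 2.15 (-9.95, SE 0.329). IGFBP5, which binds insulin-like growth factors, had 2324 ± 460 against 0.174 ± 0.268 (-10.96, SE 0.196). Of the most abundant genes in each line, 3 were shared: MT-CO1 and MT-CO2 of the mitochondrial genome, which were not called, and the elongation factor EEF1A1. EEF1A1 had 6592 ± 945 TPM in 16HBE and 12710 ± 2545 in IMR90hTERT, and was called under median-of-ratios scaling (-1.37), without IMR90hTERT replicate 1 (-1.08) and without 16HBE replicate 3 (-1.01) but not in the planned comparison (-0.94). The galectin LGALS1 (10750 ± 876 against 754 ± 214) and the thymosin TMSB10 (9959 ± 1639 against 2512 ± 634) were higher in IMR90hTERT. The median log2 fold change of all tested genes was 0.42, so a gene with no difference relative to other genes lay at that value. Under median-of-ratios scaling, which removes most of this shift, the split was 2570 higher in 16HBE and 2685 higher in IMR90hTERT, so that 48.9% of calls favoured 16HBE against 67.3% in the planned comparison; quantile normalization gave 49.7%.

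**Figure D2:**
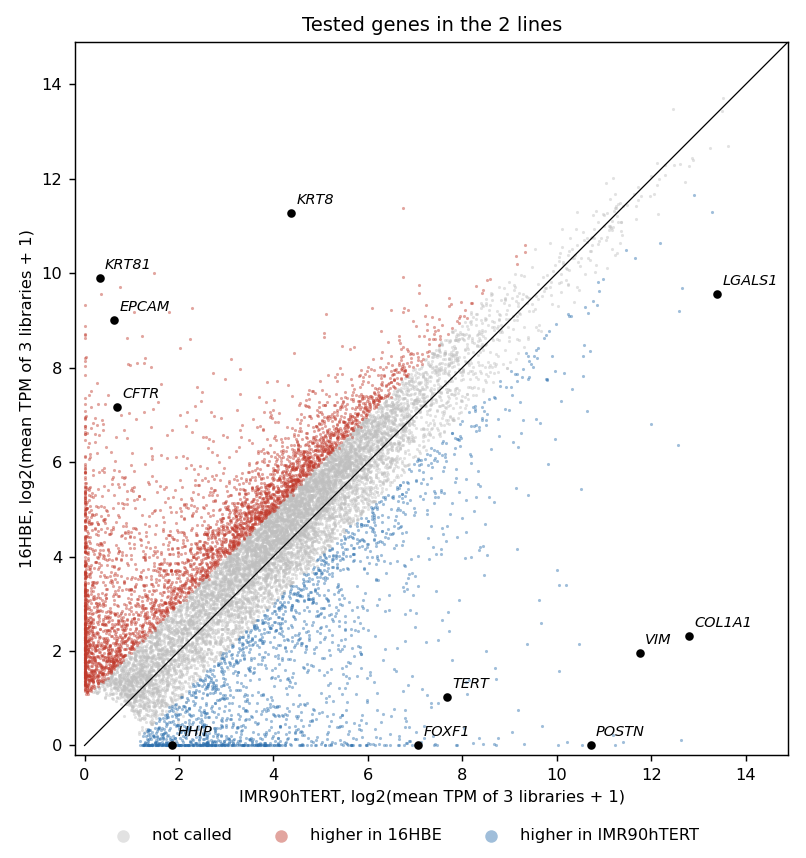
Mean expression of each tested gene in IMR90hTERT (horizontal axis) and 16HBE (vertical axis), as log2 of the mean TPM of 3 libraries plus 1, with called genes in colour and the diagonal marking equal levels; Y-linked genes and XIST are left out. COL1A1 and VIM lie far to the right of the diagonal, and KRT81 and EPCAM far above it.

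Genes of epithelial junctions and keratins were higher in 16HBE. On the list of epithelial junctions and adhesion, 39 of 40 tested genes were higher in 16HBE and none was higher in IMR90hTERT (camera adjusted p = 4.4e-15, and an adjusted p of 0.0423 with an estimated correlation). The adhesion molecule EPCAM had 515 ± 45.9 TPM against 0.536 ± 0.158 (log2 fold change 8.39, SE 0.134), and the protease inhibitor SPINT2 had 578.5 ± 10.7 against 1.07 ± 0.77 (8.19, SE 0.238). The membrane protease PRSS8 had 229 ± 21.9 TPM and was listed at 0 in IMR90hTERT. The remaining gene was DSP, for the desmosomal linker desmoplakin, at 27.8 ± 3.13 TPM in 16HBE and 16.2 ± 8.85 in IMR90hTERT (log2 fold change 0.89, limma adjusted p = 0.057); it was called, at 1.26, without IMR90hTERT replicate 1. Of 12 tested keratins 11 were higher in 16HBE, among them KRT8 (2469 ± 304 against 19.7 ± 5.21 TPM) and KRT7 (614 ± 107 against 3.84 ± 1.56). KRT10, a keratin of stratified epidermis, was not called (18.9 ± 9.50 against 16.5 ± 4.71 TPM; it was named, like every member given below because a count was small, after its values were seen). For keratins the set test gave an adjusted p of 5.83e-05, and an adjusted p of 0.0898 with an estimated correlation. The median of the epithelial list exceeded the median of all genes by 4.73 and that of the keratins by 4.38 on the log2 scale.

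Mesenchymal, matrix and contractile genes were higher in IMR90hTERT. All but 2 of the 37 tested fibroblast and mesenchymal markers were higher there and none was higher in 16HBE (camera adjusted p = 9.33e-26, and an adjusted p of 0.032 with an estimated correlation). LOX, which crosslinks collagen and elastin, had 828 ± 64.7 TPM against 0.339 ± 0.166. The 2 that were not called were S100A4 (21.9 ± 5.40 TPM in 16HBE, 29.7 ± 6.78 in IMR90hTERT) and NT5E (192 ± 22.3 and 152 ± 63.2). Of 24 tested collagens 19 were higher in IMR90hTERT (camera adjusted p = 1.24e-11, and an adjusted p of 0.032 with an estimated correlation). COL1A1 had 7136 ± 817 TPM there and 4.01 ± 1.70 in 16HBE. The 3 collagens higher in 16HBE, named because they were few, were COL17A1 of hemidesmosomes (42.7 ± 11.4 against 0.0607 ± 0.0444 TPM) and the type IV chains COL4A5 (10.3 ± 4.39 against 2.42 ± 1.39) and COL4A6 (2.94 ± 1.03 against 0.235 ± 0.137). COL7A1 and COL27A1 were not called. Of 14 contractile genes of smooth muscle and myofibroblasts, 12 were higher in IMR90hTERT and none in 16HBE (camera adjusted p = 8.45e-11, and an adjusted p of 0.0938 with an estimated correlation). The actins ACTG2 and ACTA2 had 1187 ± 194 and 420.5 ± 81.5 TPM in IMR90hTERT against 0.0521 ± 0.0902 and 1.67 ± 0.54; these actins are near-identical in coding sequence, so the share of each is uncertain. The calponin CNN1 had 115.8 ± 23.9 against 0.0713 ± 0.123. SYNPO2 and CSRP1 were not called, with log2 fold changes of -0.90 and -0.97. Laminins and integrins went both ways, with 8 of 24 higher in 16HBE and 11 higher in IMR90hTERT. The former included LAMB3, a laminin chain of epithelial basement membranes (404 ± 67.2 against 1.32 ± 0.74 TPM), and ITGB6 (123.5 ± 16.7, listed at 0 in IMR90hTERT). The latter included LAMA4 (115.4 ± 10.4 against 0.312 ± 0.403) and ITGA11, a collagen receptor subunit (49.0 ± 12.6, listed at 0 in 16HBE). Their median was -0.63 and their mean 0.21. The set test put them lower in 16HBE with an adjusted p of 0.0454, which did not hold under median-of-ratios scaling (0.21), without IMR90hTERT replicate 1 (0.0619) or with an estimated correlation (adjusted p = 0.375).

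On the TGF-beta list, 15 of 29 tested genes were higher in IMR90hTERT, none was higher in 16HBE and 14 were not called (camera adjusted p = 2.9e-07, and an adjusted p of 0.0986 with an estimated correlation). The members with the largest differences were GREM1, LTBP1, which stores latent TGF-beta in the matrix (274.5 ± 43.7 against 1.12 ± 1.05 TPM), the activin antagonist FST (805 ± 365 against 5.04 ± 1.36) and TGFBI (6047 ± 1107 against 80.9 ± 34.6). GREM1 and FST are secreted antagonists of ligands of this family and not its effectors. Of 28 matrix proteases and inhibitors, 17 were higher in IMR90hTERT and 6 were higher in 16HBE (camera adjusted p = 0.000256, and an adjusted p of 0.156 with an estimated correlation). The gelatinase MMP2 had 1028 ± 188 TPM in IMR90hTERT against 12.2 ± 5.54, and the inhibitor TIMP3 had 793 ± 130 against 7.48 ± 2.53. The membrane metalloproteinase MMP15 was higher in 16HBE, at 21.6 ± 3.48 against 0.887 ± 0.196.

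Markers of airway cell types were present in 16HBE in part. Of 14 airway basal cell markers 7 passed the filter, and 6 of these were higher in 16HBE, among them ITGB4 (149 ± 3.22 against 0.357 ± 0.19 TPM), ITGA6 (164.5 ± 20.2 against 12.0 ± 3.82) and KRT5 (17.7 ± 8.24, listed at 0 in IMR90hTERT). CAV1, the remaining one, was not called (log2 fold change -0.57). Under median-of-ratios scaling 5 of the list were higher in 16HBE and 1 was higher in IMR90hTERT. The set test for this list passed narrowly (adjusted p = 0.0467) and did not hold with a pseudocount of 0.1 (0.0588), without 16HBE replicate 1 (0.0501) or with an estimated correlation (adjusted p = 0.387). TP63, the transcription factor of basal cells, named after its values were seen, stood at 0.264 ± 0.175 TPM in 16HBE and was listed at 0 in IMR90hTERT. Of 19 secretory and goblet markers 5 passed the filter, of which LCN2, CFTR, SLPI and MUC4 were higher in 16HBE and MUC1 was not called. CFTR, the chloride channel altered in cystic fibrosis, had 143 ± 12.96 TPM against 0.599 ± 0.944 (log2 fold change 6.64, SE 0.346), and the protease inhibitor SLPI had 79.2 ± 39.4 against 0.371 ± 0.642. The set test for this list gave an adjusted p of 0.0711, and an adjusted p of 0.375 with an estimated correlation; it passed under median-of-ratios scaling (0.0202) and without 16HBE replicate 2 (0.0402). Of the secretory markers, 9 were listed at 0 in all 6 libraries. Of 10 tested multiciliated cell markers 2 were higher in 16HBE and 4 were higher in IMR90hTERT, and their median of 0.0003, mean of -0.59 and test (camera adjusted p = 0.276, and 0.568 as the adjusted p with an estimated correlation) gave no call. Higher in IMR90hTERT were DNAH5, CCDC40, TPPP3 and TUBA1A. The alpha-tubulin gene TUBA1A, which many dividing and migrating cells express, had 1173 ± 112 TPM in IMR90hTERT against 9.47 ± 3.16. HYDIN and MCIDAS were higher in 16HBE at low levels, 2.90 ± 0.82 and 1.496 ± 0.296 TPM. HYDIN, TUBA1A and EEF1A1 each share sequence with near-identical copies elsewhere, which leaves their values uncertain.

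Lists for other lung cell types held few expressed genes. Of 19 alveolar epithelial markers 8 were tested and 4 were higher in 16HBE, namely LAMP3 (32.6 ± 24.1 against 0.185 ± 0.149 TPM), RTKN2 (25.9 ± 2.53 against 4.75 ± 1.45), CLIC5 and AGER, without a call for the list (camera adjusted p = 0.474, and 0.568 as the adjusted p with an estimated correlation). LAMP3 ranged from 13.7 to 59.8 TPM among 16HBE libraries. Of 5 tested endothelial markers, EGFL7 (53.8 ± 4.28 against 6.65 ± 2.95 TPM), ROBO4, CDH5 and KDR were higher in 16HBE and the angiopoietin receptor TEK was higher in IMR90hTERT (10.4 ± 5.39 against 0.0964 ± 0.0668; camera adjusted p = 0.321, and 0.516 as the adjusted p with an estimated correlation). Only 3 of 19 leukocyte markers passed the filter, too few for the set test. These were CSF1R and CORO1A, higher in 16HBE, and the lysosomal protein CD68, higher in IMR90hTERT (43.04 ± 2.83 against 8.13 ± 1.57 TPM). The call of CORO1A, at 1.23, did not hold under median-of-ratios scaling (0.90), under quantile normalization (0.89) or without 16HBE replicate 2 (0.91). Among lung and airway transcription factors, 5 of 16 were higher in 16HBE and 10 were higher in IMR90hTERT, with a set test lower in 16HBE (adjusted p = 0.000462, and an adjusted p of 0.0928 with an estimated correlation). ELF3 (95.3 ± 12.2 against 0.16 ± 0.181 TPM) and GRHL2 (37.3 ± 3.22, listed at 0 in IMR90hTERT), both epithelial factors, were higher in 16HBE with SOX9, KLF5 and IRX2, and FOXF1 and TBX3 (41.6 ± 5.66 against 0.325 ± 0.0259) in IMR90hTERT. FOXP4 was not called. Under median-of-ratios scaling 3 of the list were higher in 16HBE. NKX2-1, the regulator of lung epithelial identity, named after its values were seen, was listed at 0 in all 6 libraries.

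**Figure D3:**
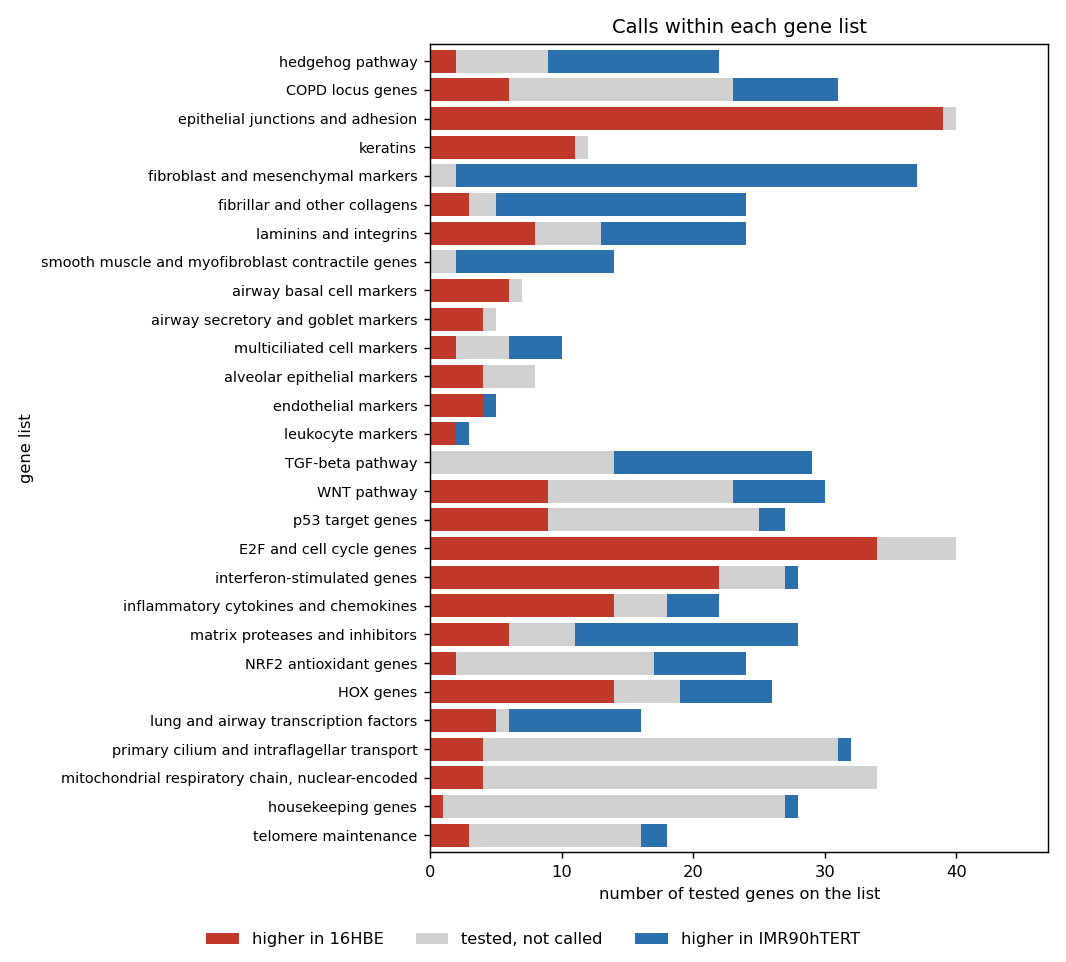
Number of tested genes on each of the 28 gene lists that were higher in 16HBE, not called, or higher in IMR90hTERT, as stacked bars starting at 0. The epithelial list shows 39 of 40 genes higher in 16HBE and the fibroblast list 35 of 37 higher in IMR90hTERT.

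Cell cycle genes were higher in 16HBE, with a spread among IMR90hTERT libraries. Of 40 E2F and cell cycle genes, 34 were higher in 16HBE and none was higher in IMR90hTERT. Examples are the thymidylate synthase gene TYMS (612 ± 57.6 against 67.2 ± 32.7 TPM, log2 fold change 3.27, SE 0.294) and the replication factors CDC6 (136 ± 17.5 against 14.99 ± 6.997) and CDC45 (114.5 ± 1.66 against 16.0 ± 8.95). The mean log2(TPM + 1) of the list was 6.56, 6.54 and 6.55 in 16HBE libraries 1, 2 and 3, and 5.33, 4.19 and 4.79 in those of IMR90hTERT. The camera adjusted p was 4.83e-05. The list mean spanned 1.14 among IMR90hTERT libraries and 0.02 among 16HBE libraries, so its members moved together in IMR90hTERT. The correlation between members, estimated over both lines, was 0.83, and the camera adjusted p was 0.568 with that estimated correlation. Under median-of-ratios scaling 27 members were called, and 31 were called without IMR90hTERT replicate 2, the library with the lowest mean.

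Interferon-stimulated genes and several cytokines were higher in 16HBE. Of 28 interferon-stimulated genes, 22 were higher in 16HBE and 1, the signalling subunit IRF9, was higher in IMR90hTERT (35.2 ± 3.72 against 15.04 ± 1.03 TPM). BST2, which tethers budding virus particles, had 144 ± 34.8 TPM in 16HBE against 4.06 ± 3.02, OASL had 28.5 ± 8.82 against 0.401 ± 0.303, and IFIT2 had 90.9 ± 27.1 against 4.69 ± 1.73 (camera adjusted p = 0.000462 for the list, and an adjusted p of 0.387 with an estimated correlation). Of 22 inflammatory cytokines and chemokines, 14 were higher in 16HBE, among them IL1A (293 ± 45.7 against 1.44 ± 0.99 TPM) and CCL5 (182 ± 80.4 against 0.102 ± 0.0491). Higher in IMR90hTERT were the chemokines CCL2 (13.2 ± 8.30 against 0.0355 ± 0.0615) and CXCL12 (13.1 ± 5.10 against 0.146 ± 0.11), with TSLP and IL11. As a set the cytokines did not pass (camera adjusted p = 0.0907, and an adjusted p of 0.331 with an estimated correlation), but they did under median-of-ratios scaling (0.0078) and without IMR90hTERT replicate 1 (0.0451). Of 27 p53 target genes 9 were higher in 16HBE, a number that was 5 under median-of-ratios scaling, and 2 were higher in IMR90hTERT (camera adjusted p = 0.297, and an adjusted p of 0.601 with an estimated correlation). They included GDF15, a secreted stress factor (210 ± 58.0 against 16.0 ± 7.99 TPM), and BTG2 (6.95 ± 1.56 against 0.534 ± 0.397), with EDA2R (0.123 ± 0.12 against 2.78 ± 0.75) and TP53INP1 in the other direction. Of 24 antioxidant genes of the NRF2 list, 7 were higher in IMR90hTERT and 2 were higher in 16HBE (camera adjusted p = 0.00417, and an adjusted p of 0.156 with an estimated correlation). The call of GPX3, one of the 2, did not hold under either centring scaling or without any 1 of 5 libraries, all but IMR90hTERT replicate 2, with log2 fold changes from 0.68 to 1.07 in those fits. CAT, for catalase, had 26.1 ± 3.37 TPM in IMR90hTERT and 3.84 ± 0.35 in 16HBE, and the exporter ABCC3 had 38.5 ± 3.73 in 16HBE and 6.01 ± 1.67 in IMR90hTERT.

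WNT and HOX genes were split between the lines. On the WNT list, 9 of 30 genes were higher in 16HBE and 7 were higher in IMR90hTERT (camera adjusted p = 0.297, and an adjusted p of 0.761 with an estimated correlation). The ligands WNT7B (21.1 ± 3.40 against 0.443 ± 0.278 TPM) and WNT10A (13.1 ± 4.02, listed at 0 in IMR90hTERT) were higher in 16HBE. WNT5A (235 ± 16.0 TPM, listed at 0 in 16HBE) and DKK3 (331 ± 25.5 against 17.3 ± 5.57) were higher in IMR90hTERT. Of 26 tested HOX genes, the transcription factors that mark position along the body axis, 14 were higher in 16HBE and 7 were higher in IMR90hTERT (camera adjusted p = 0.964, and an adjusted p of 0.976 with an estimated correlation). HOXC10 (42.5 ± 2.59 TPM) and HOXC13 (6.71 ± 2.14) were listed at 0 in IMR90hTERT. HOXB5 (24.1 ± 2.65 against 0.842 ± 0.274) and HOXA5 (44.5 ± 8.29 against 4.53 ± 1.38) were higher in IMR90hTERT. All 9 tested genes with paralog numbers 9 to 13 were higher in 16HBE, and of 13 with numbers 1 to 6, 3 were higher in 16HBE and 7 were higher in IMR90hTERT.

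**Figure D4:**
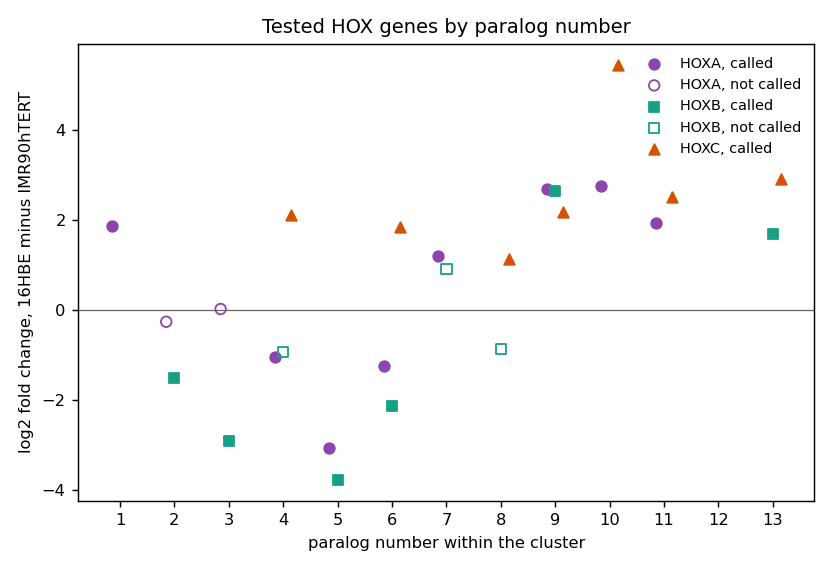
Log2 fold change, 16HBE minus IMR90hTERT, of the 26 tested HOX genes against paralog number, by cluster; filled points are called genes and open points are not called. The 9 genes numbered 9 to 13 lie above 0, and the lowest value is that of HOXB5 at -3.78.

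Of 32 genes of the primary cilium and intraflagellar transport, 4 were higher in 16HBE, among them IFT74 (34.3 ± 3.03 against 8.50 ± 2.67 TPM), DYNC2I2 and DYNC2H1, and BBS5 was higher in IMR90hTERT (5.61 ± 0.21 against 1.17 ± 0.04). The median of this list was 0.18 and its mean 0.28, below the median of all genes, so the set test leaned lower in 16HBE (camera adjusted p = 0.792, and an adjusted p of 0.923 with an estimated correlation). Of 34 nuclear genes of the respiratory chain, 4 were higher in 16HBE, namely NDUFV1 (242 ± 42.4 against 88.7 ± 3.98 TPM), NDUFV2, SDHB and ATP5MC1. NDUFV2, at a log2 fold change of 1.001, fell below the fold threshold under both centring scalings (0.57 and 0.86), with mitochondrial genome genes removed (0.9925) and without IMR90hTERT replicate 2 (0.885) or 16HBE replicate 1 (0.976) or 2 (0.977). Under median-of-ratios scaling none of the 34 was called higher in 16HBE and 4 were called higher in IMR90hTERT, so no direction can be given for this list (camera adjusted p = 0.824, and an adjusted p of 0.976 with an estimated correlation). Of 28 housekeeping genes, TBP was higher in 16HBE (37.2 ± 1.53 against 14.4 ± 1.65 TPM) and PGK1 was higher in IMR90hTERT (556 ± 94.5 against 231 ± 46.8); the call of TBP, at 1.31, did not hold under quantile normalization (0.94) or median-of-ratios scaling (0.90), which called 4 of the list higher in IMR90hTERT. Without 16HBE replicate 1, 3 housekeeping genes were higher in 16HBE and 1 in IMR90hTERT, and without IMR90hTERT replicate 1, 2 and 2. The median (0.25) and mean (0.15) of the housekeeping list were above 0 and its test leaned lower in 16HBE (camera adjusted p = 0.792, and an adjusted p of 0.923 with an estimated correlation). Of 18 telomere maintenance genes, DKC1 (130.3 ± 21.1 against 44.9 ± 8.13 TPM), WRAP53 and CTC1 were higher in 16HBE, and TERT and STN1 were higher in IMR90hTERT; without IMR90hTERT replicate 1, 5 were higher in 16HBE (camera adjusted p = 0.964, and an adjusted p of 0.976 with an estimated correlation). In all, 14 of 27 tested lists passed the set test, 5 higher and 9 lower in 16HBE, and 3 of them passed with an estimated correlation: epithelial junctions, fibroblast markers and collagens. Some lists share genes, such as FOXF1 on the hedgehog, fibroblast and lung transcription factor lists, so their passes are not independent results. Groupings of the 6 libraries that mixed the lines called 0 genes and passed 7 to 14 lists in the same test with the preset correlation. These groupings keep part of the line difference, so they do not show how often a list passes without one. For each of the 28 lists, the numbers of members called were the same when adjusted over the list alone as over all genes tested.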

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

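Fits on genes with a mean TPM of at least 10 or on protein-coding genes, and list member counts under each setting, were alternatives added after the data were seen. Against 3946 genes higher in 16HBE and 1919 higher in IMR90hTERT, median-of-ratios scaling gave 2570 in favour of 16HBE and quantile normalization gave 2572, because both centre the genes. Testing against a log2 fold change of 1 gave 2021 and 1200, being stricter by construction. Dropping the fold threshold gave 7207 and 3115, and genes with a mean TPM of at least 10 gave 2242 and 983, as fewer genes were tested. Leaving out each library in turn gave 3940 to 4252 and 1957 to 2021, and 93.1% to 96.4% of the calls were kept. Under median-of-ratios scaling 76.5% of calls were kept, under quantile normalization 76.2%, and in none of the 14 settings compared was a call reversed. With HHIP listed at 0 in 16HBE, its log2 fold change follows the pseudocount: -1.774 with 1, -2.53 with 0.5 and -4.615 with 0.1. With a pseudocount of 1 it lost its call when tested against a log2 fold change of 1 (adjusted p = 0.0598), a stricter test by construction. It was not tested when a TPM of at least 5 was required, and kept its call under the other alternatives for pseudocount, filter, scaling, variance model, block and left-out library (adjusted p from 7.39e-05 to 0.00607). TERT kept its call under all of these, with adjusted p from 3.13e-08 to 1.46e-05. The variance models and fold thresholds for these 2 genes were added after the data were seen. With the replicate block the counts were 3951 and 1926, and 12 lists passed, without laminins and integrins (adjusted p = 0.0545) and airway basal markers (0.0532). Libraries with the same number did not deviate together (r of 0.00818, -0.07 and -0.038 across genes), and 1 of 6 correlated best with its own number, so the numbers were not taken as pairs.

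Of the lists, 14 passed the set test, 3 passed with an estimated correlation, 23 with fry and 13 to 15 without 1 library. The estimates for the hedgehog list (-0.00584) and the collagens (0.0024) were below the preset 0.01, yet their adjusted p rose. Losses with the estimated correlation are thus not all due to members that vary together. The fewer degrees of freedom of that test raise small p-values whatever the correlation. Genes restricted to 16HBE numbered 922 with a limit of 0.5 TPM in the other line and 209 with at least 5 TPM required, against 500; those restricted to IMR90hTERT numbered 583, 144 and, with exactly 0 required, 207, against 332. These follow from the limits. Without 1 library the numbers were 549 to 581 and 361 to 380.

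The direction of some list tests turned, and the cause was not tested except where given here. With fry, the adjusted p was 0.0728 for laminins and integrins, 0.942 for WNT, 0.0151 for the cilium and 0.0172 for housekeeping genes. The last 2 thus passed with fry as higher in 16HBE. In fry the members are compared with 0, and in camera with other genes, whose median was 0.42. The means of laminins and integrins (0.21), cilium (0.28) and housekeeping genes (0.15) lie between these values, so the 2 tests differ in direction by what they compare. The WNT mean (-0.024) does not. With no filter it was 0.896 for the cilium and 0.853 for housekeeping genes. With a TPM of at least 5 it was 0.562 for HOX genes and 0.942 for telomere genes. Median-of-ratios scaling gave 0.479 for the respiratory chain and 0.696 for telomere genes, and quantile normalization gave 0.583 for housekeeping and 0.827 for telomere genes. Without 1 library, telomere genes ranged from 0.857 to 0.995.

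Some genes that were not called changed sign. Median-of-ratios scaling and quantile normalization, which centre the genes, gave log2 fold changes of -0.20 and -0.15 for SMO, -0.0419 and -0.0536 for EVC2, -0.0923 and -0.0354 for STK36, -0.23 and -0.19 for RIN3, -0.0841 and -0.0457 for EEFSEC, -0.23 and -0.20 for INTS12, -0.29 and -0.25 for EGLN2, and -0.042 and -0.0075 for ZGPAT. MT-CO2 was at -0.26 under the former and MT-CO1 at 0.0656 under the latter. Without 1 library MT-CO1 ranged from -0.156 to 0.0638 and MTCL1 from -0.142 to 0.0705; the cause was not tested. Counted over pairs of a named gene and an alternative setting, so that 1 gene can count several times, 24 fold changes turned. Another 11 gained a call, 29 lost one and 2214 did neither. For pairs of a list test and an alternative setting these numbers were 14, 16, 20 and 379. Depth is unknown, so it cannot be said which low genes it limits.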

Other observations

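The tests of a common scaling factor, of abundant genes, of carried-over RNA, of cell cycle differences between libraries and of HOX order were chosen after the results were seen; the test on genes with a mean TPM of at least 10 was added after the unequal split was seen and before its own outcome was.

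More genes were called higher in 16HBE, 67.3% of calls. Among genes with a mean TPM of at least 10 the share was 69.5%, which argues against detection of low genes as the whole cause. These genes keep the shift between the lines, with a median log2 fold change of 0.44. The share thus cannot tell whether detection of low genes adds to the skew. Median-of-ratios scaling was first set down as the test of abundant genes and gave 48.9% (45.9% among genes with a mean TPM of at least 10), inside the range written for that cause, but centring fixes this outcome, so a common scaling factor between the lines cannot be told apart from a real excess. A later test removed the 145 genes with a mean TPM of at least 1000, which took 41.7% ± 1.3 of TPM in IMR90hTERT and 32.2% ± 0.62 in 16HBE (SD, n = 3 each), and gave 58.7%. Abundant genes above that limit, 1 choice among many, may thus account for part of the skew and not for all of it, and a biological difference between the lines stays open.

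Each line held traces of genes typical of the other. COL1A1 in 16HBE stood at 0.0562% of its IMR90hTERT level. If carried-over RNA or reads gave that, 11 further abundant fibroblast and collagen genes would reach the same share, and 5 lay below 0.2 of it; DCN, POSTN and COL3A1 were listed at 0 where 0.833, 0.945 and 1.35 TPM were needed, which argues against this source for COL1A1. Over all protein-coding genes above 1000 TPM, the only 3 listed at 0 were these same genes, so this count is no separate evidence. At most 0.00918 were expected from how often genes at such levels are listed at 0, or 0.0427 at the lowest levels and share. In the other direction EPCAM stood at 0.104%, and 3 of 13 epithelial genes lay below 0.2 of the level needed, all listed at 0 and 1 of them needing over 0.5 TPM, and this list does not decide. Over all protein-coding genes with a mean above 300 TPM, 5 of 488 were listed at 0, among them KRT19, LCN2, S100A9 and SAA1, where at most 0.36 were expected, which counts against 16HBE material in the IMR90hTERT libraries. At the lowest level of each gene and the lowest EPCAM share it was 2 of 420 with at most 1.01 expected. Of 6 limits tried from 100 to 1000 TPM, 3 gave a Poisson p below 0.01 at mean levels and 0 at the lowest levels, against 3 and 1 for COL1A1. The zeros thus do not go beyond the spread between libraries, and this source stays open for EPCAM. Low expression in the lines themselves was not tested.

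Cell cycle genes differed among IMR90hTERT libraries, by 1.14 in mean log2(TPM + 1) against 0.02 among 16HBE libraries. The lowest 16HBE library still exceeded the highest IMR90hTERT library by 1.21, more than the median difference of all genes (0.42), which argues against slow growth of single IMR90hTERT libraries as the whole cause. A difference in growth between the lines or cultures stays open and was not tested.

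A hypothesis is that 16HBE may carry a more posterior HOX profile than IMR90hTERT. Paralog number and log2 fold change correlated across the 26 tested HOX genes with Spearman's rho of 0.65 and Pearson's r of 0.59 (permutation p = 0.00043 for rho, two-sided, adjusted 0.0017 over 4 relations). This restates, on the same genes, the pattern that prompted it, so the p-values give the hypothesis no independent support and it stays open. Genes of a cluster are neighbours and not independent replicates. Within clusters rho was 0.49 for HOXA (10 genes, permutation p = 0.15, adjusted 0.15), 0.75 for HOXB (9 genes, exact permutation p = 0.025, adjusted 0.05) and 0.75 for HOXC (7 genes, exact permutation p = 0.066, adjusted 0.088).

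Of the 10 splits of the 6 libraries into 3 and 3, the real one called 5865 genes and the highest other called 0, so 1 split gave as many. For gene lists 2 splits gave as many, with 14 in the real split and 14 in the highest other. All 9 splits that mixed the lines passed 7 to 14 lists while calling 0 genes. Each sets 2 libraries of one line and 1 of the other against the reverse, so part of the line difference stays in it. That difference also widens the spread within each side, which lowers the number of genes called. The splits thus do not show how often a list passes without a difference between lines. How far a pass with the preset correlation can be trusted stays open. The splits are too few for a share under 0.05.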
